A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

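Expression was measured on 18 single-colour Affymetrix arrays of Saccharomyces cerevisiae strain BY4742. Per the labels' protocols, cultures in YPD, a rich medium, received nonylphenol dissolved in ethanol at 1 or 5 mg/L in the middle of exponential growth, or ethanol alone, and were collected 120 or 180 min later. Each of the 6 combinations of dose and time had 3 arrays, called biological replicates in the labels. Total RNA was isolated with the RNeasy Mini Kit, and biotin-labelled aRNA was made from 100 ng of it with the GeneChip 3' IVT Express Kit, per the labels' protocols.

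The deposited values were RMA signals, which are background corrected, normalized between arrays and summarised per probe set. RMA, affy and limma were named per the submitters' processing notes, and their versions and settings were not given in the sources used here. The deposited values were read as log2 from their distribution, since over all arrays they ran from 0.41 to 13.74, the range of RMA values on that scale; the base is not stated in the sources used here. The table held 10928 probe sets, of which 7245 had a name in the platform annotation, 7244 of them with 1 gene symbol. The S. cerevisiae probe sets tested numbered 5498 and stood for 5449 genes, with 12 symbols updated from the gene table supplied with the data. The 47 genes with more than 1 probe set kept each probe set as its own measurement. Of these genes, 17 at 120 min and 21 at 180 min were called by only some of their probe sets in the comparison of 5 mg/L with control, and 1 at each time was called in opposite directions. PHO11, HXT7 and YAR066W were read by probe sets of a type that several transcripts can share, and PHO12 and HXT6 were matched to none. The other 1747 named probe sets belonged to another yeast species and served as the background, 213 were controls of the manufacturer, and 3470 had no name and were kept apart. The background level was the percentile 95 of the other-species means, 1.86, and the median S. cerevisiae probe set stood at 7.93. Probe sets carry no genome position in these data, so none is given.

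A group-means model was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend or robust settings). P-values were adjusted by the Benjamini-Hochberg method over the 5498 probe sets in each of 9 comparisons, with a threshold of 0.05. Fold changes come from the same fit, with group means of 3 arrays each. Their standard errors (SE) use 1 spread per gene, pooled over all 18 arrays in 6 groups and moderated by eBayes. The spread of groups outside a comparison thus enters its SE. The comparisons were each dose with control at each time, the doses with each other at each time, the difference between the times in the effect of each dose, and the control groups of both times. The changes over time at 1 and 5 mg/L were added after the data had been examined. P-values measure the spread between these arrays, and the number of arrays limits the precision.

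Gene lists, 40 in number, were written from general knowledge of yeast before the data were examined, as were the comparisons, the tests, the rule for naming genes and all alternatives except those described as added. Of their 1035 genes, 7 stood in more than 1 list. Each list was tested with camera in limma at the preset correlation of 0.01, adjusted over the lists of a comparison, then with an estimated correlation and with fry, which asks only whether a list's own genes moved. Counts within a list were also computed with p-values adjusted over the list alone. Named genes were the 12 largest rises and 12 largest falls in each comparison of a dose with control, among genes with an adjusted p under 0.05 whose 3 treated arrays all lay above, or all below, the 3 control arrays. For the other comparisons these were the 5 largest each way, without the array condition for differences between times, and 3 each way where nothing passed. Up to 4 called members of each list were named with the smallest p, and genes that mark the strain and mating type were read in every group.

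The same steps were tested on simulated data built from the real arrays. For a comparison like 1 mg/L with control, simulated log2 changes of 0.25, 0.5, 1 and 2 were called for 40, 94, 100 and 100% of 50 genes each, with 9 wrong calls among 5498 genes. For a difference between times at 1 mg/L the shares were 16, 82, 96 and 100%, with 8 wrong calls. The 50 genes of each size were changed at once, and scatter was drawn separately for each array. With fewer genes changed the adjusted threshold is stricter, so these shares may overstate what could be called at 1 mg/L. Correlations of effects across genes were compared with those of simulated unchanged groups that share the same control arrays. Genes are not independent replicates, so no p-value was attached to these correlations.

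Replicate numbers were checked as a sign of shared cultures or days by correlating the residuals of arrays with the same number. Every pair was above 0.1 only for 1 mg/L and control at 120 min, with r = 0.25, 0.41 and 0.37 across genes. A fit with the replicate number as a block called 23 probe sets there, 21 of them among the 25 called without it; 4 of the 24 named genes (YGR035C, BSC1, ALD5 and SAM3) and 2 of 16 lists lost their calls. Alternatives tried were other scalings between arrays, filters on dim or foreign probe sets, other variance settings, array weights, stricter thresholds, the block, fits on the compared arrays alone, and the removal of each array in turn. A scaling of each array on the 36 poly-A control probe sets above background was added after the data had been examined. Figures were drawn with matplotlib 3.10.9.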

Results

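Transcript levels were measured in BY4742, a haploid laboratory yeast of mating type alpha, after exposure to nonylphenol, an alkylphenol formed when some industrial surfactants break down. The question stated for the series was how transcription across the genome responds to the compound at a pair of concentrations, here 1 and 5 mg/L, each compared with cultures given ethanol alone. Arrays numbered 18, with 3 for each of 6 groups: control, 1 mg/L and 5 mg/L, collected after 120 or 180 min. On single arrays, 98.0 to 99.3% of the 5498 S. cerevisiae probe sets lay above the background level. Replicate arrays correlated at r = 0.994 to 0.999. The first principal component held 71.2% of the variance and the second 11.5%.

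Genes that mark the strain and mating type were read first. The alpha-specific genes SAG1, the alpha agglutinin, and STE3, the receptor for a-factor, had mean log2 values of 11.58 and 10.02 in controls at 120 min. URA3 and LYS2, which the standard genotype of this strain lacks, stood at 0.95 and 1.54, both under the background level of 1.86. LEU2, which the standard genotype lacks as well, stood at 3.03, above background, so its value did not mark the deletion. Why was not tested. HIS3 read 9.34, so its probe set did not report the partial deletion in this strain, and it was lower at 5 mg/L than in controls by log2 -0.50 at 120 min and -0.54 at 180 min. LYS2 and URA3 stayed under background in all 6 groups, at no more than 1.57 and 1.24, and neither passed in any comparison of a dose with control.

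All changes are relative to the deposited scaling between arrays. Poly-A control transcripts, bacterial sequences supplied for adding to RNA samples, read 0.78 higher (log2, SE 0.21, 3 arrays per group) at 5 mg/L than in controls at 120 min and 0.24 higher (SE 0.24) at 180 min. When arrays were scaled on these transcripts, an alternative chosen after seeing the data, all genes shifted by log2 -0.78 at 120 min and -0.24 at 180 min in the comparison of 5 mg/L with control. A rise smaller than the shift became a decrease on that scale, and falls became larger. This scaling also carried the scatter of the poly-A readings between replicates into every gene, which by itself lowers counts of called probe sets. At 5 mg/L and 120 min, where the shift was large, the counts rose instead. For 1 mg/L against control the same scaling shifted all genes by 0.05 and -0.05. The poly-A differences behind these shifts had SEs of 0.14 and 0.37, so they were within their own scatter. Since the shift is the same for all genes, which list medians change sign on this scale depends on their size alone and is no test of a list. For the genes named as the largest changes against control, all 3 treated arrays lay above, or all below, the 3 control arrays, an order that chance gives for 10% of genes.

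**Figure D1:**
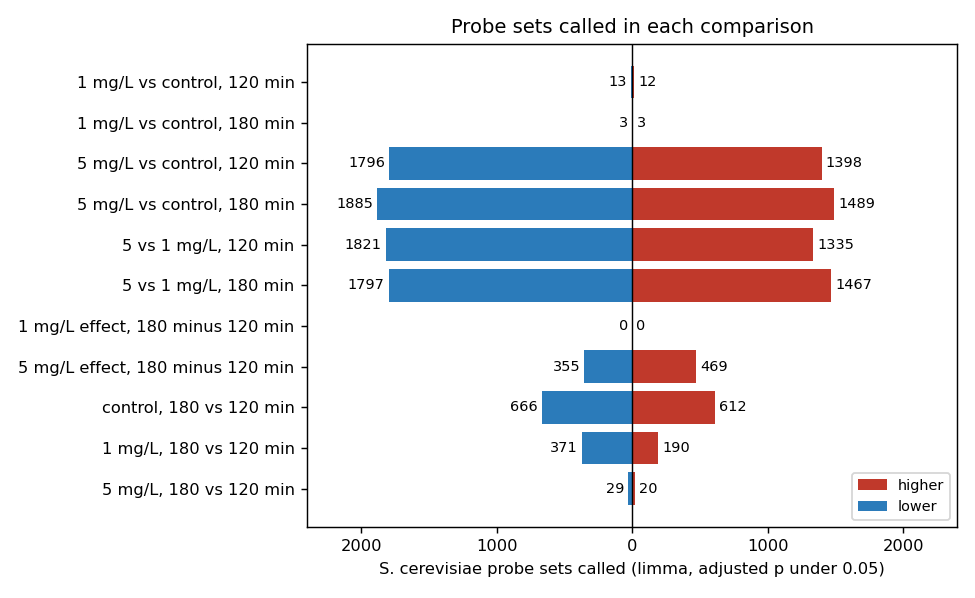
Number of S. cerevisiae probe sets called higher (red, right) and lower (blue, left) by limma at an adjusted p under 0.05 in each comparison, counted along the horizontal axis. Exposure to 5 mg/L called 3194 and 3374 probe sets at 120 and 180 min, against 25 and 6 for 1 mg/L.

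At 1 mg/L and 120 min, changes against control were below 2-fold for every called probe set. TMA10 (YLR327C), which encodes a ribosome-associated protein, was 1.5-fold higher than in controls (log2 0.59, SE 0.08, n = 3 arrays per group, limma adjusted p = 0.00137). RSB1, a transporter of sphingoid long-chain bases, was 1.43-fold higher, and PDR5, the main multidrug efflux pump, was 1.3-fold higher (log2 0.38, SE 0.06). The glycogen genes GPH1, GSY1 and GLC3 rose by log2 0.46, 0.38 and 0.37, and OLE1, the fatty acid desaturase, by 0.41. PHO5 (YBR093C), the secreted acid phosphatase, was 1.68-fold lower (log2 -0.75, SE 0.12, adjusted p = 0.00302). ARO10 and ARO9, which act in the breakdown of aromatic amino acids, changed by -0.69 and -0.61, and HXT1, a low-affinity glucose transporter, by -0.54. IZH4, FRE2, GRE2, ATG40 and YGR035C also rose, and PRM7, BSC1, OAC1, PHO11, PHO8, ALD5, SAM3 and BAT2 also fell, BSC1 to the background level.

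Among the lists at 1 mg/L and 120 min, the phosphate starvation genes had 3 members lower (PHO5, PHO11 and PHO8) and 14 not called, with 5 lower when adjusted over the list alone and a median of -0.11 (camera adjusted p = 3.56e-11). The general stress genes had 3 of 31 members higher, 7 when adjusted over the list alone, and all 31 estimates lay above 0 with a median of 0.18 (adjusted p = 1.12e-20; adjusted p = 0.0939 with an estimated correlation). Of 17 drug efflux genes, RSB1 and PDR5 rose, with 5 higher and 1 lower when adjusted over the list alone (median 0.08, adjusted p = 0.000701; adjusted p = 0.168 with an estimated correlation). FRE2, a ferric reductase, was the single called member of the 23 iron uptake genes, over all genes and over the list alone (median 0.15, adjusted p = 3.4e-06; adjusted p = 0.268 with an estimated correlation), and the shift was lost without NP1_120 replicate 3 (adjusted p = 0.0721). The amino acid biosynthesis list had 0 of 40 called over all genes by limma and 3 lower when adjusted over the list alone (median -0.04, adjusted p = 0.000198; adjusted p = 0.147 with an estimated correlation), and its shift was lost without NP1_120 replicate 1 (adjusted p = 0.0788). In all, 10 lists shifted up and 6 down, and the phosphate list was the 1 that held with an estimated correlation (adjusted p = 0.00102). Only the phosphate, general stress and drug efflux lists kept their shift without each array in turn. Every other list lost it without at least 1 array, with a camera adjusted p up to 0.776 for endoplasmic reticulum folding genes. On the poly-A scaling the medians of 5 of these 16 lists, amino acid biosynthesis among them, turned from below to above 0.

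The 25 probe sets called for 1 mg/L at 120 min (12 higher, 13 lower) became 14 without control_120 replicate 1 and 15 without control_120 replicate 3. Of the 24 named genes, 10 kept their call without each array in turn: TMA10, IZH4, RSB1, GPH1, PHO5, ARO10, PRM7, ARO9, HXT1 and OAC1. In a fit on the compared arrays alone 17 probe sets were called, 13 of them among the 25, and FRE2, GRE2, OLE1, ATG40, PDR5, GSY1, GLC3, BSC1, PHO8, ALD5, SAM3 and BAT2 lost their calls. Limma counted 238 probe sets at an unadjusted p under 0.05 on the deposited scaling, where chance alone gives 275. With array weights the adjusted count was 252, and on the poly-A scaling it was 0 by limma.

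At 1 mg/L and 180 min, 6 probe sets were called and all can be named. YGR035C, a gene of unknown function, was 1.53-fold higher than in controls (log2 0.61, SE 0.08, n = 3, limma adjusted p = 0.00321), RSB1 was 1.52-fold higher (log2 0.60, SE 0.07, adjusted p = 0.00169), and ATG40, a receptor for autophagy of the endoplasmic reticulum, was 1.3-fold higher. EEB1, an enzyme of ethyl ester synthesis, was 1.47-fold lower (log2 -0.55, SE 0.08), ARO10 was 1.42-fold lower, and BAT2, a branched-chain aminotransferase, was 1.20-fold lower. YGR035C, RSB1, ATG40, ARO10 and BAT2 were called in the same direction at 120 min.

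No member of the phosphate list was called over all genes at 1 mg/L and 180 min, where 5 were lower when adjusted over the list alone; the median was -0.10 (camera adjusted p = 3.13e-07), and this list again held with an estimated correlation (adjusted p = 0.0086). The iron uptake genes had 0 called over all genes and 2 higher over the list alone, with 22 of 23 estimates above 0 and a median of 0.13 (adjusted p = 7.33e-12; adjusted p = 0.213 with an estimated correlation). Ribosome biogenesis genes had a median of 0.09 with 0 of 55 called by limma over all genes or when adjusted over the list alone (adjusted p = 7.33e-12; adjusted p = 0.343 with an estimated correlation). In all, 11 lists shifted up and 1 down, of which only the phosphate list held with an estimated correlation, and 6 of the 12 medians changed sign on the poly-A scaling. Only the phosphate, iron uptake and ribosome biogenesis lists kept their shift without each array in turn. Every other list lost it without at least 1 array, with a camera adjusted p up to 0.649 for cell wall genes. At an unadjusted p under 0.05 limma counted 198 probe sets, fewer than the 275 that chance gives.

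The 6 calls at 1 mg/L and 180 min became 3 without control_180 replicate 1, 2 without control_180 replicate 2, 2 without control_180 replicate 3, 3 without NP1_180 replicate 1 and 2 without NP1_180 replicate 3. RSB1 and YGR035C kept their calls in each case. A fit on the compared arrays alone called RSB1 and EEB1, and YGR035C (adjusted p = 0.229), ATG40, ARO10 and BAT2 lost their calls; array weights gave 106 calls and the poly-A scaling 0.

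At 5 mg/L and 120 min, the largest rises included genes of meiosis and sporulation, the inositol synthesis gene INO1, the a-specific gene AGA2 and the stress gene HSP12. MAM1 (YER106W), a kinetochore protein of the first meiotic division, was 24.1-fold higher than in controls (log2 4.59, SE 0.18, n = 3 arrays per group, limma adjusted p = 1.11e-11). YGR035C was 9.22-fold higher (log2 3.20, SE 0.08, adjusted p = 4.96e-14) and INO1, which makes inositol phosphate for phospholipid synthesis, 8.62-fold higher (log2 3.11, SE 0.14). The sporulation genes SPR3 and SPS100 rose by log2 3.36 and 2.66, AGA2, the a agglutinin subunit, by 2.97, and HSP12, a membrane-associated stress protein, by 2.62. OPT2 (YPR194C), an oligopeptide transporter, was 4.19-fold lower (log2 -2.07, SE 0.12, adjusted p = 3.81e-10). MIS1, the mitochondrial enzyme of one-carbon metabolism, changed by -1.36, HXT4, a high-affinity glucose transporter, by -1.28, ARO10 by -1.26, and the ribosome assembly genes HAS1 and RRP5 by -1.22 and -1.09. LSO1 and BAG7 also stood among the largest rises, as did SAE3, SPO19 and YLR412C-A, whose control means of 1.34, 1.80 and 1.70 lay under the background of 1.86, so that the size and rank of their rises are not known; ARO9, WSC4, NSR1, ERC1, PPT1 and ABP140 were further named falls.

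**Figure D2:**
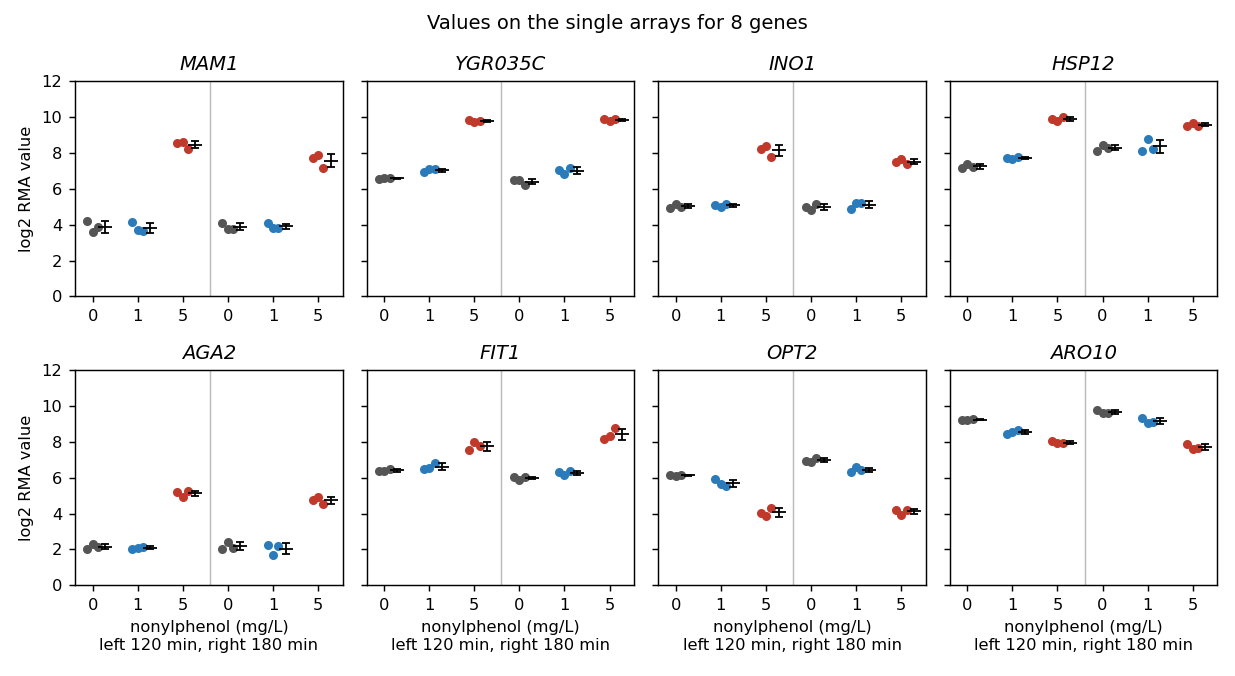
Log2 RMA values (vertical axis) on single arrays for MAM1, YGR035C, INO1, HSP12, AGA2, FIT1, OPT2 and ARO10 at 0, 1 and 5 mg/L, with 120 min on the left and 180 min on the right of each panel; points are arrays, and bars are the mean and SD of 3. The rises at 5 mg/L exceeded the shifts of 0.78 and 0.24 by which the poly-A scaling would lower them, with log2 values of 4.59 for MAM1 and 3.20 for YGR035C at 120 min.

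Lists of stress genes were compared at 5 mg/L and 120 min. Of the 31 general stress genes, 29 rose and 2 were not called, both over all genes and when adjusted over the list alone (median 0.87, camera adjusted p = 1.26e-13; adjusted p = 0.0983 with an estimated correlation); DDR2 rose by 2.11 and MSC1 by 1.29. Of 25 heat shock and chaperone genes, 15 rose, 1 fell and 9 were not called, with 2 lower when adjusted over the list alone; HSP42 rose by 1.72 and SSA4 by 1.45 (median 0.26, adjusted p = 1.67e-05; adjusted p = 0.0983 with an estimated correlation). The 31 oxidative stress genes split into 17 higher, 6 lower and 8 not called, unchanged over the list alone, with GRE2 at 1.34 and TSA2 at 1.05 (median 0.18, adjusted p = 0.00944; adjusted p = 0.225 with an estimated correlation). Drug efflux genes had 12 members higher, 3 lower and 2 not called, with 13 higher when adjusted over the list alone, among them ICT1 at 1.83, RSB1 at 1.48, PDR15 at 1.45 and the regulator PDR3 at 0.90 (median 0.32, adjusted p = 0.000466; adjusted p = 0.104 with an estimated correlation). Iron uptake genes had 19 of 23 higher, also over the list alone, with TIS11, an mRNA-binding regulator of iron use, at 1.79 and the siderophore transporter ARN2 at 1.64 (median 0.90, adjusted p = 1.49e-09; adjusted p = 0.0983 with an estimated correlation). DNA damage genes rose for RNR3 (1.63) and HUG1 (1.45), with 10 higher, 2 lower and 12 not called, the same over the list alone (median 0.08, adjusted p = 0.0291; adjusted p = 0.201 with an estimated correlation). Autophagy and vacuole genes had 12 higher, 2 lower and 8 not called, unchanged over the list alone, with ATG8 at 1.60 (median 0.25, adjusted p = 0.00186; adjusted p = 0.138 with an estimated correlation).

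Lists of sporulation and a-specific genes were compared at 5 mg/L and 120 min. Of the 27 sporulation genes, 19 rose, 1 fell and 7 were not called, with 2 lower when adjusted over the list alone (median 0.44, camera adjusted p = 1.18e-05; adjusted p = 0.0983 with an estimated correlation). Of the 7 a-specific genes, 6 rose in total and when adjusted over the list alone (median 1.20, adjusted p = 0.000119; adjusted p = 0.0837 with an estimated correlation). These were AGA2, MFA2 (2.49), BAR1 (1.93), MFA1 (1.20), ASG7 (1.08) and STE6 (0.27), of which STE6 lost its call without control_120 replicate 2 (0.18), NP5_120 replicate 1 (0.24) or NP5_120 replicate 3 (0.23) and would fall below 0 on the poly-A scaling. STE2, the alpha-factor receptor, had a value of 0.09 and was not called. Among the alpha-specific genes, STE3 and MF(ALPHA)2 changed by -0.54 and -0.43. S. cerevisiae probe sets with control levels of 2 to 4 rose in general, with a median of 0.45, and other-species probe sets had a median of -0.03.

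Lists with medians below 0 were also found at 5 mg/L and 120 min. Of 55 ribosome biogenesis genes, 36 fell, 6 rose and 13 were not called, with 38 lower when adjusted over the list alone; RPA135, a subunit of RNA polymerase I, changed by -0.75 and IMP4 rose by 0.92 (median -0.34, camera adjusted p = 0.000103; adjusted p = 0.374 with an estimated correlation). Of 127 cytosolic ribosomal protein genes, 56 fell, 3 rose and 68 were not called, with 2 higher when adjusted over the list alone, RPS9B changing by -0.61 and RPL5 by -0.33 (median -0.16, adjusted p = 0.000451; adjusted p = 0.65 with an estimated correlation). Probe sets with control levels over 10 had lower values in general, with a median of -0.11 at 120 min and -0.12 at 180 min. Amino acid biosynthesis genes had 23 lower, 8 higher and 9 not called, with 9 higher over the list alone; LYS4 changed by -0.77 and LYS20 rose by 0.85 (median -0.21, adjusted p = 0.0171; adjusted p = 0.247 with an estimated correlation). Genes of the G1 and S phases had 16 lower, 2 higher and 11 not called, also over the list alone, with the G1 cyclin CLN1 at -0.74 and the S-phase cyclin CLB6 at -0.67 (median -0.26, adjusted p = 0.00668; adjusted p = 0.374 with an estimated correlation). Hexose transporters went both ways, with HXT5, GAL2 and HXT1 at 2.09, 1.91 and 0.92 beside the fall of HXT4, and their list was not called.

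Further lists that shifted up at 5 mg/L and 120 min were those of peroxisomal beta-oxidation, glucose-repressed gluconeogenesis, anaerobic, nitrogen-catabolite, osmotic, sulfur and mitochondrial ribosomal protein genes, and translation factors shifted down, each with an adjusted p of 0.0843 to 0.603 with an estimated correlation; the mitochondrial ribosomal shift was lost without NP5_120 replicate 1 (adjusted p = 0.0759). Some members moved against their list: MDH2, a gluconeogenic malate dehydrogenase, changed by -0.59, OPT2 stood among the nitrogen-catabolite genes, and SAM3, a permease for S-adenosylmethionine in the sulfur list, changed by -0.88. In total 16 lists shifted up and 5 down, none called with an estimated correlation. On the poly-A scaling the medians of 13 of the 21 lists turned from above to below 0, and the general stress, iron and a-specific lists kept medians above 0, at 0.08, 0.12 and 0.42. Median, mean and test differed in sign for fatty acid and phospholipid genes (median -0.14, mean 0.05, test down) and for endoplasmic reticulum folding genes (median -0.00, mean 0.24, test up), where INO1 took part in both lists; neither list was called.

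Limma called 3194 of 5498 probe sets at 5 mg/L and 120 min (58.1%), 1398 higher and 1796 lower; 193 were at least 2-fold higher and 10 at least 2-fold lower. On the poly-A scaling the split was 95 higher and 4278 lower.

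At 5 mg/L and 180 min, MAM1, INO1 and AGA2 were again high, and genes of iron acquisition stood among the largest rises while respiratory genes fell. MAM1 was 12.9-fold higher than in controls (log2 3.69, SE 0.18, n = 3 arrays per group, limma adjusted p = 7.55e-11), LSO1 was 12.4-fold higher (log2 3.63, SE 0.15) and YGR035C 10.9-fold higher (log2 3.45, SE 0.08). TIS11 rose by 2.48 and FIT1 and FIT2, cell wall mannoproteins that retain siderophore iron, by 2.45 and 2.36. GTO3, a glutathione transferase, rose by 2.88 and MFA2, a gene for a-factor, by 2.65. OPT2 was 7.28-fold lower (log2 -2.86, SE 0.12, adjusted p = 1.13e-11) and ARO10 3.89-fold lower (log2 -1.96, SE 0.08). HXT4 changed by -1.66, the mitotic cyclin CLB1 by -1.28, INH1, an inhibitor of the mitochondrial ATP synthase, by -1.24, and QDR2, a multidrug transporter, by -1.20. YMR317W also rose, as did YLR412C-A from a control mean of 1.65, under background, and ARO9, YMR230W-A, YBR184W, SPS4, MIS1 and HXT7 also fell.

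Iron uptake genes showed the widest shift of the lists at 5 mg/L and 180 min apart from the a-specific genes, with 22 of 23 higher, also when adjusted over the list alone (median 1.19, camera adjusted p = 3.85e-13; adjusted p = 0.0983 with an estimated correlation). ARN2 and SIT1, siderophore transporters, rose by 2.27 and 2.20 and FET3, the multicopper ferroxidase, by 1.12. The a-specific genes had 6 of 7 higher in total and over the list alone (median 1.25, adjusted p = 0.000177; adjusted p = 0.0967 with an estimated correlation). STE2 rose by 0.28, and lost its call without control_180 replicate 1 (0.28), control_180 replicate 2 (0.23), NP5_180 replicate 2 (0.25) or NP5_180 replicate 3 (0.22), and its value was -0.04 under quantile normalization; the poly-A scaling would lower it by nearly its whole size. STE6 had 0.08 and was not called. Sporulation genes had 19 higher, 2 lower and 6 not called, the same over the list alone, with SPR3 at 2.28 and SPS100 at 2.28, while SPS4, a gene induced in sporulation, changed by -1.17 (median 0.39, adjusted p = 0.000108; adjusted p = 0.14 with an estimated correlation). General stress genes had 24 higher, 4 lower and 3 not called, also over the list alone, with XBP1, a repressor, at 2.13 and DDR2 at 1.91 (median 0.44, adjusted p = 6.55e-06; adjusted p = 0.247 with an estimated correlation). Of the heat shock genes 17 rose and 2 fell, with 18 higher over the list alone (median 0.37, adjusted p = 5.21e-06; adjusted p = 0.103 with an estimated correlation). Drug efflux genes had 11 higher and 4 lower, with 5 lower over the list alone, PDR15 at 1.85 and PDR3 at 1.24 (median 0.52, adjusted p = 0.00151; adjusted p = 0.152 with an estimated correlation).

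Respiratory genes fell at 5 mg/L and 180 min, with 28 of 33 lower, 2 higher and 3 not called, and 29 lower when adjusted over the list alone (median -0.52, camera adjusted p = 1.23e-06; adjusted p = 0.103 with an estimated correlation). CYC1, cytochrome c, changed by -0.89 and COX4, a subunit of cytochrome c oxidase, by -0.83. Of the cytosolic ribosomal protein genes 77 fell and 3 rose, also over the list alone (median -0.21, adjusted p = 2.02e-06; adjusted p = 0.595 with an estimated correlation). Purine and pyrimidine synthesis genes had 15 lower, 2 higher and 9 not called, the same over the list alone, with URA4 at -1.04, URA1 at -0.99 and the uridine permease FUI1 at -1.06 (median -0.17, adjusted p = 0.00203; adjusted p = 0.141 with an estimated correlation). Genes of daughter cell separation rose, 11 of 15 in total and over the list alone, with DSE2 at 1.13 and the chitinase CTS1 at 0.68 (median 0.39, adjusted p = 0.000538; adjusted p = 0.152 with an estimated correlation). Cell wall, anaerobic, autophagy, DNA damage, gluconeogenesis, nitrogen-catabolite, peroxisome and oxidative stress lists also shifted up, with adjusted p of 0.0983 to 0.494 with an estimated correlation, and the oxidative stress shift was lost without control_180 replicate 3 (adjusted p = 0.0562); HUG1 rose by 2.15 and the anaerobic mannoprotein DAN1 by 1.22. In total 15 lists shifted up and 3 down, and on the poly-A scaling the medians of 4, those of oxidative stress, peroxisome, autophagy and DNA damage genes, turned below 0.

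**Figure D3:**
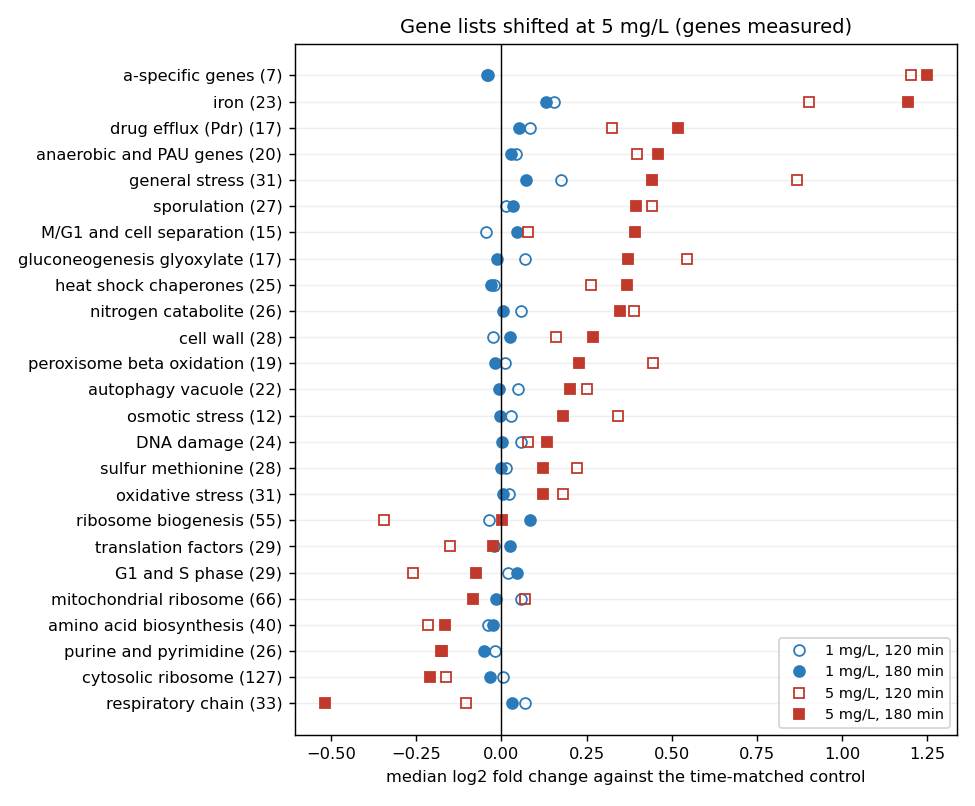
Median log2 fold change against the control of the same time (horizontal axis) of each gene list shifted at 5 mg/L, with the number of genes measured in brackets, for 1 mg/L (circles) and 5 mg/L (squares) at 120 min (open) and 180 min (filled). Iron uptake genes had medians of 0.90 and 1.19 at 5 mg/L and a-specific genes 1.20 and 1.25; on the poly-A scaling each square lies 0.78 lower at 120 min and 0.24 lower at 180 min, which turns 13 and 4 medians below 0.

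Limma called 3374 probe sets at 5 mg/L and 180 min (61.4%), 1489 higher and 1885 lower; 168 were at least 2-fold higher and 21 at least 2-fold lower. On the poly-A scaling 550 were called, 175 higher and 375 lower.

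The doses were compared directly. At 120 min MAM1 was 24.9-fold higher at 5 mg/L than at 1 mg/L (log2 4.64, SE 0.18, n = 3 arrays per group, limma adjusted p = 1.09e-11), and SPR3, INO1 and AGA2 were higher by 3.24, 3.06 and 3.03; SAE3 was also higher, with a mean of 1.23 at 1 mg/L, under background. OPT2, HXT4, MIS1, HAS1 and HXT7 were lower, at -1.62, -1.54, -1.29, -1.17 and -1.14. At 180 min MAM1, LSO1, YMR317W, GTO3 and YGR035C were higher by 3.66, 3.31, 2.85, 2.85 and 2.84, and OPT2, HXT4, ARO10, YMR230W-A and HXT7 were lower, at -2.31, -1.77, -1.45, -1.35 and -1.32. The general stress genes had 26 higher and 2 lower of 31 at 120 min, also over the list alone (median 0.66, camera adjusted p = 6.96e-10; adjusted p = 0.123 with an estimated correlation). Iron uptake genes had 20 of 23 higher at 180 min, with 21 over the list alone (median 1.11, adjusted p = 9.12e-12; adjusted p = 0.0812 with an estimated correlation), and respiratory genes 29 of 33 lower at 180 min, also over the list alone (median -0.52, adjusted p = 2.58e-08; adjusted p = 0.0812 with an estimated correlation). PHO11, lower at 1 mg/L than in controls at 120 min, was higher at 5 mg/L than at 1 mg/L by 1.44. Limma called 3156 probe sets at 120 min, 1335 higher and 1821 lower, and 3264 at 180 min, 1467 higher and 1797 lower. On the poly-A scaling, which shifted all genes by -0.84 and -0.19, the splits were 69 higher and 4512 lower at 120 min, where the general stress median turned below 0, and 173 higher and 165 lower at 180 min.

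Effects were compared across genes. The effects of 5 mg/L at 120 and 180 min correlated at r = 0.84 (Spearman 0.77), with 1046 probe sets higher at both times where 379 would overlap by chance, 1247 lower at both times against 616, and 61 called in opposite directions. For 1 mg/L the times correlated at r = 0.15 and Spearman -0.03, and r lay between -0.08 and 0.36 when single arrays were left out; it was -0.07 without NP1_120 replicate 3, -0.01 without control_180 replicate 1, -0.08 without NP1_180 replicate 2 and 0.36 without NP1_120 replicate 1. Genes are not independent replicates, so these correlations carry no p-value. At 120 min, 10 of the 12 probe sets higher at 1 mg/L were also higher at 5 mg/L, where chance gives 3.05, and 7 of the 13 lower ones were also lower, where chance gives 4.25, while 2 were called in opposite directions. At 180 min the overlap was 3 of 3 higher (0.813 by chance) and 2 of 3 lower (1.03 by chance). The doses share their control arrays, so part of this excess may come from those arrays. Effects of different times share none. Of the probe sets called at 1 mg/L and 120 min, 9 of 12 higher (3.25 by chance) and 7 of 13 lower (4.46 by chance) kept that direction at 5 mg/L and 180 min. Another 7 were called in opposite directions, and r was 0.09. For 1 mg/L at 180 min and 5 mg/L at 120 min, 3 of 3 higher and 1 of 3 lower overlapped (0.763 and 0.98 by chance), and r was 0.13. The correlation between doses was 0.34 at 120 min and 0.31 at 180 min, where simulated unchanged groups gave 0.50 each time, and the covariances were 0.0133 and 0.0116 against simulated values of 0.00365 and 0.00365.

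The controls changed between 120 and 180 min. HSP12 was 2.03-fold higher at 180 min (log2 1.02, SE 0.13, n = 3 arrays per group, limma adjusted p = 5.79e-05), and EGO4, OPT2, HAC1 and STF2 were higher by 0.95, 0.84, 0.84 and 0.79. HXT1 was 2.19-fold lower (log2 -1.13, SE 0.08, adjusted p = 4.45e-07), and TOD6, a repressor of ribosome biogenesis genes, HXT2, FRE7 and YNL095C were lower, at -0.91, -0.80, -0.76 and -0.76. Ribosome biogenesis genes had 47 of 55 lower, 49 when adjusted over the list alone (median -0.39, camera adjusted p = 1.89e-27; adjusted p = 0.0663 with an estimated correlation), with DBP2 at -0.76. General stress genes had 22 of 31 higher, 26 over the list alone, GPH1 at 0.73 among them (median 0.38, adjusted p = 6.81e-13; adjusted p = 0.2 with an estimated correlation). Respiratory genes had 24 of 33 higher, 25 over the list alone, with QCR10 at 0.58 (median 0.29, adjusted p = 3.11e-11; adjusted p = 0.0663 with an estimated correlation), and mitochondrial ribosomal protein genes 38 of 66 higher, 51 over the list alone (median 0.22, adjusted p = 1.85e-13; adjusted p = 0.257 with an estimated correlation). Iron uptake genes had 9 lower and 1 higher, with 13 lower over the list alone, FRE1 at -0.67 among them (median -0.20, adjusted p = 0.000574; adjusted p = 0.429 with an estimated correlation). The poly-A scaling shifted all genes by -0.13, which left these list medians on the same side of 0. Limma called 1278 probe sets, 612 higher and 666 lower; the count was 740 without control_120 replicate 1, 678 without control_120 replicate 3, 646 without control_180 replicate 2, and 1 on the poly-A scaling.

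The effect of 5 mg/L differed between the times for 824 probe sets, 469 higher and 355 lower in the later effect. The difference was 1.15 for HXT1 (SE 0.11, limma adjusted p = 2.17e-05, n = 3 arrays in each of 4 groups), 1.11 for YMR317W, 1.10 for FIT1, 1.04 for YAR068W and 1.00 for YAR066W. It was -1.33 for HSP12 (SE 0.18, adjusted p = 0.000435), -1.13 for EGO4, -1.08 for SPR3 and -1.07 for SRT1, and it was also below 0 for SAE3, whose size is not known because both control means lay under background. Ribosome biogenesis genes had 34 of 55 higher, 41 over the list alone (median 0.36, camera adjusted p = 9.87e-19; adjusted p = 0.145 with an estimated correlation), with DBP2 at 0.81 and NSR1 at 0.66. Respiratory genes had 20 of 33 lower, 23 over the list alone (median -0.36, adjusted p = 6.1e-11; adjusted p = 0.109 with an estimated correlation), and CYC1 was at -0.62. General stress genes had 14 of 31 lower, with 17 lower and 1 higher over the list alone, GPH1 at -0.69 (median -0.31, adjusted p = 2.16e-08; adjusted p = 0.347 with an estimated correlation). Iron uptake genes had 12 of 23 higher, 13 over the list alone, and ARN1 was at 0.91 (median 0.36, adjusted p = 3.92e-07; adjusted p = 0.343 with an estimated correlation). On the poly-A scaling, which shifted all genes by 0.54, the respiratory and general stress medians turned above 0, and 5 probe sets were called.

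Of these 824 probe sets, 611 had been called in the opposite direction in the controls over time. Both contain the same 6 control arrays, which alone gives opposite signs: the correlation across genes was -0.84, and -0.71 in simulated unchanged groups. The covariance was -0.0433, against -0.00732 in those simulated groups. For a change over time at 5 mg/L, 34 of the 824 were called. The count of 824 became 449 without control_120 replicate 1, 427 without control_120 replicate 3, 436 without NP5_120 replicate 1, 403 without control_180 replicate 2, 540 without NP5_180 replicate 2 and 435 without NP5_180 replicate 3.

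For 1 mg/L, limma called 0 probe sets for a difference between the times, with 139 at an unadjusted p under 0.05 (275 by chance), 159 called with array weights and 1 with the replicate block. The largest differences that did not pass were 0.35 for OAC1, 0.25 for LTV1 and 0.25 for PAU17 on the higher side, and -0.60 for IZH4 (SE 0.11, adjusted p = 0.0825), -0.56 for OLE1 and -0.54 for MLS1 on the lower side.

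Changes over time within the treated groups were added after the controls had been seen. At 1 mg/L 561 probe sets changed from 120 to 180 min, 190 higher and 371 lower, of which 168 and 314 were called in the same direction in controls, and the changes correlated across genes at r = 0.84. At 5 mg/L 49 changed, 20 higher and 29 lower, and the correlation with the controls was -0.06.

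**Figure D4:**
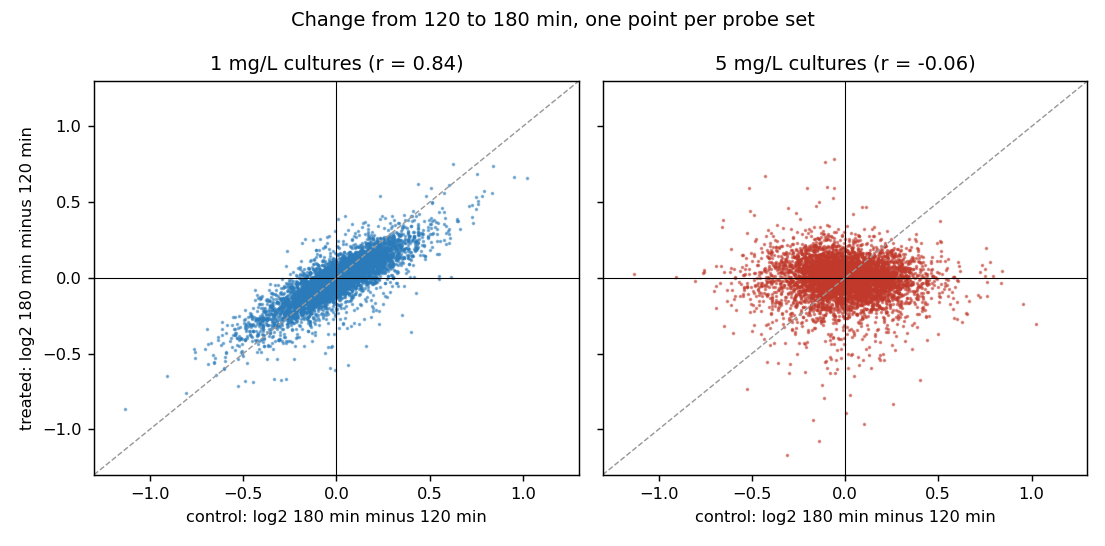
Change in log2 value from 120 to 180 min in controls (horizontal axis) and in treated cultures (vertical axis) at 1 mg/L (left) and 5 mg/L (right), with each point a probe set and the diagonal marking equal change. The changes correlated at 0.84 for 1 mg/L and -0.06 for 5 mg/L.

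**Figure D5:**
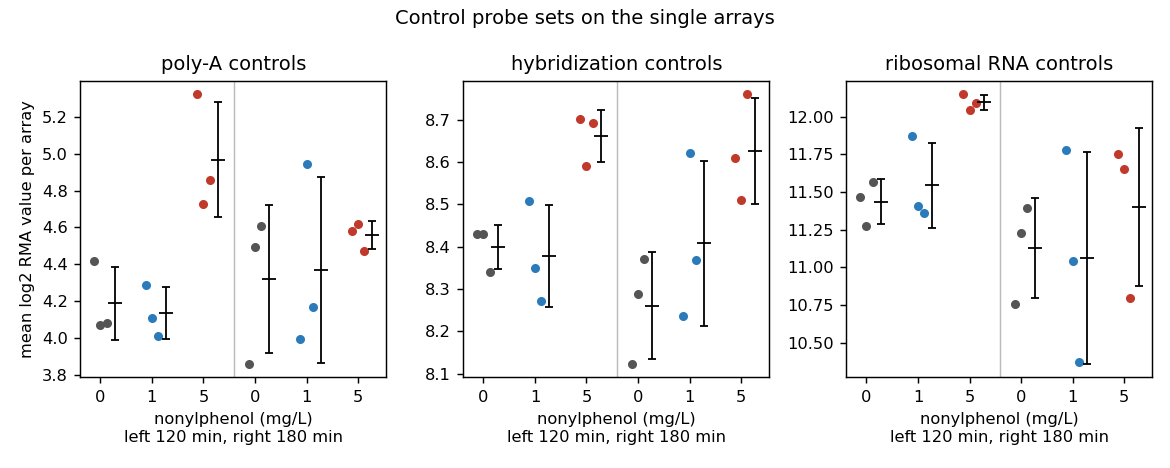
Mean log2 RMA value per array (vertical axis) of the poly-A, hybridization and ribosomal RNA control probe sets at 0, 1 and 5 mg/L, with 120 min on the left and 180 min on the right of each panel; points are arrays, and bars are the mean and SD of 3. The poly-A controls at 5 mg/L lay 0.78 above the controls at 120 min and 0.24 above at 180 min.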

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

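The tests of the slope over time and of earlier changes at 5 mg/L, and all tests on the poly-A controls were chosen after their results had been seen; the correlation with the change over time at 1 mg/L, itself an added comparison, was chosen after the difference at 5 mg/L had been seen, and the regrouping of arrays was chosen before.

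The effect of 5 mg/L differed between 120 and 180 min by a test of the difference itself for 824 probe sets. Among them, the later effect was higher for HXT1 (1.15), YMR317W (1.11), FIT1 (1.10), YAR068W (1.04) and YAR066W (1.00). It was lower for HSP12 (-1.33), EGO4 (-1.13), SAE3 (-1.09, of uncertain size, as both control means lay under background), SPR3 (-1.08) and SRT1 (-1.07). These values are differences between effects and include the change of the controls over time. By themselves they do not show that a gene rose or fell at 5 mg/L. List medians differed upward for ribosome biogenesis (0.36), iron uptake (0.36), daughter cell separation (0.36), G1 and S phase (0.21), cell wall (0.17) and translation factor genes (0.094). They differed downward for respiratory (-0.36), general stress (-0.31), citrate cycle (-0.24), mitochondrial ribosomal (-0.23), peroxisomal (-0.23), sporulation (-0.22) and gluconeogenic genes (-0.19), and on the poly-A scaling these 7 medians turned above 0. None of the 13 lists held with an estimated correlation, and the sporulation difference was lost without any of 7 single arrays (adjusted p up to 0.083) and the gluconeogenic one without any of 5 (up to 0.078): control_120 replicate 3, NP5_120 replicates 2 and 3, control_180 replicate 3 and NP5_180 replicate 3 for both, and control_120 replicate 2 and NP5_180 replicate 1 for sporulation genes. The count of 824 was 449 without control_120 replicate 1, 427 without control_120 replicate 3, 436 without NP5_120 replicate 1, 403 without control_180 replicate 2, 540 without NP5_180 replicate 2 and 435 without NP5_180 replicate 3.

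The difference between times at 5 mg/L correlated across genes at -0.66 with the change over time at 1 mg/L, which shares no array with it. Unchanged groups simulated with separate scatter on each array gave -0.0017, so scatter of that kind is argued against. Scatter shared by same-numbered arrays was not part of that simulation. Residuals of control and 1 mg/L arrays correlated at 0.25, 0.41 and 0.37 at 120 min and at 0.52, 0.36 and -0.30 at 180 min. Such sharing would also push the correlation below 0. The covariance behind the -0.66 was -0.0266, however. In simulated unchanged groups, full sharing of the 6 control arrays gave a covariance of only -0.00732. These values argue against shared scatter as the whole source, while a part of it is not excluded. By construction the difference is the change over time at 5 mg/L minus that of the controls. A smaller change at 5 mg/L than in controls therefore restates it and is no separate cause. Over time, 1278 probe sets were called in controls and 49 at 5 mg/L, so the controls moved more than the 5 mg/L cultures. Among the 561 genes that changed over time at 1 mg/L, the slope of the 5 mg/L change was 0.0323 of the control slope. Part of the control change may already have taken place by 120 min at 5 mg/L. Of these genes 390 were called at 5 mg/L against control at 120 min. Among them 276 (70.8%) had moved in the direction of the 1 mg/L change and 114 in the opposite one. A stress response with shared genes, or scatter shared by control and 1 mg/L arrays, would give the same. Of 100 regroupings of the arrays, 12 gave as many calls, the real one included, so that count does not exclude chance. The 11 others kept the groups of at least 1 time whole, with up to 3892 calls, and so carried the effect of 5 mg/L itself. The 78 that mixed the groups at both times gave 0 at most by limma. Mixing counts the dose effect as spread between arrays, so this 0 was largely fixed beforehand. Neither kind of regrouping tests the difference between times.

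The poly-A controls, outside the main measurement, read 0.78 higher at 5 mg/L than in controls at 120 min on all 3 arrays (exact two-sided permutation p = 0.1, the smallest possible). Ribosomal RNA probe sets read 0.66 higher at 120 min, and hybridization controls 0.26 and 0.37 higher at 120 and 180 min. The poly-A median of 0.77 exceeded 99.99% of random gene lists of like level, of which the highest reached 0.84. The 36 poly-A probe sets read only the dap, lys, phe and thr transcripts, while the random lists drew separate genes. Their medians therefore vary too little for a fair comparison, and a general rise of weakly measured probe sets is not excluded. More labelled target is argued against, if hybridization controls were added in equal amounts. It would raise poly-A transcripts and genes alike, which normalization between arrays takes out, and would lower the hybridization controls relative to the genes. Those controls read higher instead, by 0.26 (SE 0.05) at 120 min and 0.37 (SE 0.10) at 180 min, on all 3 arrays each time. Poly-A rose by 0.52 (SE 0.19) over the hybridization controls at 120 min. A lower share of messenger RNA in the total RNA at 5 mg/L may explain the rise at 120 min, in line with the 0.66 of the ribosomal RNA probe sets, but at 180 min these changed by 0.28 (SE 0.36) and poly-A minus hybridization controls by -0.13 (SE 0.20). Total and messenger RNA were not measured, and unequal addition of the poly-A transcripts stays open too.

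For 1 mg/L, 7 lists differed between the times by a test of the difference: ribosome biogenesis (0.11), daughter cell separation (0.12), translation factors (0.063), cell wall (0.051), general stress (-0.14), gluconeogenesis (-0.11) and mitochondrial ribosomal genes (-0.072). None held with an estimated correlation, the poly-A scaling turned the cell wall and translation factor medians, and the count of lists was 4 without control_120 replicate 1, 4 without control_120 replicate 3 and 12 without NP1_120 replicate 3. The cell wall, gluconeogenic and mitochondrial ribosomal differences were lost without any of 8, 6 and 5 single arrays, with adjusted p up to 0.605, 0.231 and 0.266. For cell wall genes these were control_120 replicates 1 and 3, NP1_120 replicates 1 and 2, control_180 replicates 2 and 3 and NP1_180 replicates 1 and 3. For gluconeogenic genes they were control_120 replicates 1 and 3, NP1_120 replicate 3, control_180 replicate 1 and NP1_180 replicates 1 and 2, and for mitochondrial ribosomal genes control_120 replicates 1 and 3, NP1_120 replicate 2, control_180 replicate 2 and NP1_180 replicate 1. Since limma called 0 genes (139 at an unadjusted p under 0.05, 275 by chance), all 100 regroupings reached that count by necessity, which tests nothing; the highest gave 293, and what those arrays share was not tested.

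Of 372 probe sets without a name and above background, not used in the comparisons, 64 were higher and 49 lower at 5 mg/L at 120 min, and 57 higher and 71 lower at 180 min; the same probe set rose most at both times, by 4.09 and 3.81.

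Regrouping 3 against 3 arrays allows 10 splits, too few for a share under 0.05. Splits that mix the groups also count the difference between groups as spread between arrays. Low counts there were thus largely fixed where many genes changed. The real split alone, 1 of 10, reached its count for 5 of the dose comparisons and for the controls over time: 25 at 1 mg/L and 120 min, 3194 and 3374 at 5 mg/L, 3156 and 3264 between doses and 1278 in controls, where the highest other split gave 0, or 1 between doses at 180 min. For 1 mg/L at 180 min 2 of 10 did, with 6 calls for the real split and 125 when control replicate 1 was grouped with treated replicates 1 and 3, which points to a structure of these 6 arrays other than dose.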

How the results depend on the processing

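Array weights changed the counts of genes most at 1 mg/L, to 252 at 120 min and 106 at 180 min, and gave 159 and 2203 for the differences between times at 1 and 5 mg/L and 2861 for the controls over time. A log2 change of at least 1 left 0, 203, 0 and 189 genes for 1 and 5 mg/L at 120 min and then at 180 min, 160 and 173 between doses, 9 for the difference at 5 mg/L and 2 in controls, and an adjusted p under 0.01 left 3 for 1 mg/L at 180 min, 258 for the difference at 5 mg/L and 590 in controls. A fit on the compared arrays alone gave 17 for 1 mg/L at 120 min, 13 shared with the 25, with 12 of 24 named genes losing their calls, 2 for 1 mg/L at 180 min and 2217 in controls. The replicate block gave 1 for the difference at 1 mg/L and 2206 in controls. The poly-A scaling, chosen after seeing the data, gave 0 and 0 at 1 mg/L, 550 at 5 mg/L and 180 min, 338 between doses at 180 min, 5 for the difference at 5 mg/L and 1 in controls. It subtracted each array's own poly-A mean, with an SD at 180 min of 0.40 in controls and 0.51 at 1 mg/L, against a median gene SE of 0.07. This added spread between replicates, which by itself lowers such counts. For 5 mg/L at 120 min, against control and against 1 mg/L, the counts rose on this scaling instead, with nearly all probe sets called lower. For the other alternatives the cause was not tested beyond the stricter thresholds' own construction.

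Camera with the estimated correlation called 1, 0, 1 and 0 lists for 1 and 5 mg/L at 120 and then 180 min and 0 in the 5 other comparisons, and fry, which asks another question, called 3, 33, 1 and 34, 32 and 35 between doses, and 0 for the difference at 1 mg/L. Spearman correlations were 0.77 between times at 5 mg/L, -0.035 between times at 1 mg/L, a reversal, and 0.29 between doses at 120 min. STE2 at 5 mg/L and 180 min reversed to -0.040 under quantile normalization. The cause was not tested.

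Leaving out single arrays gave 14 to 22 genes for 1 mg/L at 120 min, 2842 to 3035 for 5 mg/L, 2 to 9 and 3007 to 3189 at 180 min, 2839 to 3096 and 2880 to 3128 between doses, 0 to 0 and 403 to 1160 for the differences between times, and 646 to 1149 in controls. Lists numbered 11 to 14, 21 to 21, 9 to 13, 17 to 19, 18 to 22, 17 to 21, 4 to 12, 11 to 14 and 10 to 15 in the same order. These counts do not show which lists were kept, and at 1 mg/L most lists lost their shift without at least 1 array. Correlations ran from 0.80 to 0.87 between times at 5 mg/L, -0.078 to 0.36 at 1 mg/L, with reversals to -0.068, -0.012 and -0.078 without NP1_120 replicate 3, control_180 replicate 1 and NP1_180 replicate 2, and between doses from 0.23 to 0.36 at 120 min and 0.22 to 0.36 at 180 min. Dim genes near the background of 1.86 limit what a change at low signal can show.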

Other observations

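The lists and their tests were planned; the tests on random lists and on LYS2 were chosen after the results had been seen.

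Phosphate genes split at 5 mg/L, where their list had not shifted: 5 rose, 5 fell and 7 were not called at 120 min, over all genes and when adjusted over the list alone. PHM8, a nucleotidase, rose by 1.15 (SE 0.09, n = 3 arrays per group) and PHO11 by 0.94, while PHO5, chosen after its values were seen, changed by -0.85 and VTC2, a part of the polyphosphate polymerase complex, by -0.61. At 120 min PHO5 was thus lower at both doses, and PHO11 lower at 1 mg/L and higher at 5 mg/L. The PHO11 probe set may also read PHO12, so the reversal cannot be assigned to PHO11 alone. Proteasome genes also split, with 9 higher, 7 lower and 18 not called at 120 min, 6 lower over the list alone, and RPN4, the regulator of proteasome genes, higher by 0.87. CTR3, a copper transporter, rose by 1.33 at 120 min and 1.44 at 180 min, although the zinc and copper list was not called at either time. PUT1, an enzyme of proline use, and UGA1, an enzyme of GABA use, rose by 1.44 and 0.87 at 120 min. All rises named here exceeded the shift of the poly-A scaling.

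Osmotic stress genes rose at 120 min for 7 of 12, with 1 lower, the same over the list alone, SIP18 by 1.54 and GRE1 by 1.08; their list median turned below 0 on the poly-A scaling. CYB2, a lactate dehydrogenase, and ADY2, an acetate transporter, rose by 1.48 and 1.38. The anaerobic genes CYC7 and PAU4 rose by 1.00 and 0.86.

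The rise of a-specific and sporulation genes in an alpha strain was weighed against a general rise of dim genes. Among 10000 random lists of like control level, the a-specific median of 1.20 exceeded 99.6% (random median 0.35). The random lists drew separate genes, while the a-specific genes may vary together. Medians of such lists may thus vary too little for a fair comparison, and a general rise of dim genes is not excluded for the a-specific list. The sporulation median of 0.44 exceeded 85.6% (random median 0.32), so a general rise of dim genes may account for that list. Cells of another strain in the 5 mg/L cultures could not be told apart from a change within the alpha cells. LYS2 stood at 1.43 at 5 mg/L and 120 min, under the background of 1.86, and URA3 stayed under it as well, but the genotype of such cells is not known. The a-specific genes moved unevenly. At 120 min AGA2 rose by 2.97, STE2 was not called, and STE6 lost its call without NP5_120 replicate 1 (0.24). At 180 min AGA2 rose by 2.54, STE6 was not called, and STE2 lost its call under quantile normalization (-0.04). No biological explanation was tested.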
